A study of Homo sapiens with 8 samples.

How the data were processed

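Total RNA from transfected HEK293 cells was profiled by RNA sequencing. HEK293 is an established human embryonic kidney line. The 8 libraries came from cells given a control siRNA, an siRNA against AUF1, an empty vector, a Flag-tagged AUF1 isoform (p37, p40, p42 or p45) or all of these isoforms together, and each of these groups held 1 library. Per the labels' protocols, RNA was extracted with Trizol and 100 ng was turned into cDNA and amplified by single-primer isothermal amplification with a NuGEN Ovation kit. This kit copies RNA with and without a poly(A) tail and leaves ribosomal RNA out. The cDNA was then sheared, made into libraries with an Illumina ChIP-seq kit and 18 cycles of PCR, and sequenced on a Genome Analyzer II. No statement on strand was given in the sources used here, so reads of a gene and of its antisense partner were treated as inseparable.

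The deposited tables list 1 FPKM value per transcript and library, with a lower and an upper bound, per the file headers. FPKM is the number of fragments normalised to transcript length and to all mapped fragments of a library. The submitters' processing notes name TopHat2 2.0.6, Cufflinks 2.0.2, Cuffdiff and the genome build hg19, and the annotation release is not given in the sources used here. A coverage column, which holds the estimated read depth over each transcript, was also deposited per the file headers. Coverage divided by FPKM was a single constant in each library, so it served as a measure of relative depth. It was 0.246 for the control siRNA library, 0.322 for AUF1 siRNA, 0.214 for the empty vector, 0.319 for p37, 0.262 for p40, 0.345 for p42, 0.215 for p45 and 0.213 for all isoforms. The number of reads is unknown, so no interval that needs counts was computed. The deposited bounds cover the uncertainty of estimation within a library and no biological spread.

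Each table held 167516 to 172153 transcripts, of which 160318 to 160340 had Ensembl identifiers and the rest had been assembled from the reads. The tables held 160485 different Ensembl transcripts, and 136915 of them matched GENCODE release 29, which was used for gene symbols, gene types, transcript sequence and exon lengths. A further 16138 were placed with a gene through the gene or cluster given for them in the tables. All coordinates are hg19 positions from the deposited tables. Transcripts shorter than 300 nt were left out, because assembled features of 42 to 96 nt held the highest FPKM values, between 2991620 and 40745900. FPKM was summed over the transcripts of each of 44366 genes, including those with the deposited status LOWDATA, 32573 to 33555 per library. The sums were divided by a median-of-ratios factor per library, computed from 13463 genes at 1 FPKM or more in all 8 libraries, and these factors ran from 0.934 to 1.065.

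Ratios were taken as log2(value + 1 FPKM), which understates the change of genes with low values. A gene was tested in a comparison when the mean of its libraries was 5 scaled FPKM or more, no transcript of it had a failed status, and it was above 0 in each library compared. A gene was called higher or lower at a log2 ratio of 1 or more in size. With 1 library in each group there was no replicate check and no p-value was computed. Counts of called genes were instead set beside the counts for all 28 pairs of libraries, and the separation of the 5 overexpression libraries from both controls beside the other splits of these 7 libraries into 5 and 2, with HNRNPD and its pseudogene left out for the higher genes. The overlap among the 5 overexpression comparisons, which share the empty vector library, was set beside 100 simulations of unchanged libraries that share 1 control, with noise drawn from the difference between both control libraries in 20 expression bins.

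The 27 gene lists were fixed before the data were examined, as were the groups, the comparisons, the thresholds and the first set of processing alternatives. A list's median log2 ratio was placed as a percentile among 10000 random lists of equal size matched on mean expression in 20 bins. It was called apart below percentile 2.5 or in the equally wide upper tail, and a list with fewer than 5 tested members was given values only. The lists covered AUF1 relatives and other AU-rich-element-binding proteins, AUF1 target mRNAs, 2 groups of DNA repair genes, DNA replication, mitosis, telomere maintenance, p53 targets, ribosomal proteins, translation factors, mRNA decay, microRNA machinery, long noncoding RNAs, RNA polymerase III products, histones, nuclear-encoded and mitochondrially encoded respiratory genes, interferon response, unfolded protein response, heat shock proteins, immediate early genes, cholesterol synthesis, glycolysis and hypoxia, splicing, and marker genes of fibroblasts, of a cervical carcinoma line and of HEK293.

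Named genes followed a fixed rule. For the knockdown they were the 10 highest and 10 lowest ratios among called genes that also differed 2-fold the same way from the other control. For overexpression they were up to 10 genes per direction with the largest separation of all 5 libraries from both controls, and the 3 highest and 3 lowest per comparison that passed against both controls. Up to 4 members per list with the largest ratios, 5 genes per direction for opposite movement, HNRNPD, NEAT1 and MALAT1 completed the rule. Unnamed loci and sex-specific genes were skipped, and some genes that met the rule are not reported here. Genes chosen otherwise are said to be chosen after their values were seen.

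The processing alternatives were pseudocounts of 0.1 and 5 FPKM, FPKM as deposited, scaling by the 75th percentile, minimum means of 1, 20 or no FPKM, no length filter, and the other control library. Alternatives chosen after seeing the data were a length-weighted sum, in which FPKM was multiplied by transcript length before summing, the inclusion of genes listed at 0, and the omission of the p45 or the p40 library. The length-weighted sum approximates the amount of RNA sequenced from a gene and is meant to move less when reads are reassigned between its short and long transcripts. It does so only in part, because reads assigned to transcripts under 300 nt are left out of it. In departure from the plan, a failed status in any of the 8 libraries excluded a gene, and genes listed at 0 in a compared library were counted separately. The procedure was tested on simulated data. For the knockdown comparison, on 10032 genes, it recovered 83.3% of 90 genes changed 3-fold and 98.8% of 85 genes changed 8-fold, and 9.5% of unchanged genes passed the threshold. For the 5 overexpression libraries, on 10365 genes, it recovered 96.0% of genes raised 8-fold. Random lists of 30 genes were called apart in 5.0% of cases without a shift and in 100.0% with a shift of 0.5. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.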

Results

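AUF1, encoded by HNRNPD, is an RNA-binding protein that recognises AU-rich and U-rich sequences in mRNA and long noncoding RNA and is known for its roles in mRNA decay and translation. Its isoforms p37, p40, p42 and p45 arise by alternative splicing. The libraries measured how the HEK293 transcriptome differed when AUF1 was lowered by siRNA or raised by overexpression. There were 8 libraries with 1 in each group, so no difference below has a replicate check. The AUF1 siRNA library was compared with the control siRNA library, and each of the 5 overexpression libraries with the empty vector library. Values are scaled FPKM sums per gene. Relative depth, as coverage per 1 FPKM, ran from 0.213 in the all-isoform library to 0.345 in the p42 library, and 24240 to 27125 genes were above 0.

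HNRNPD (ENSG00000138668, hg19 chromosome 4, 83273651 to 83295656) stood at 296.6 FPKM with the control siRNA and at 167.3 FPKM with the AUF1 siRNA. The deposited bounds of its transcripts, scaled and summed, were 258.0 to 335.1 and 133.7 to 201.0. Such sums are not a deposited interval for the gene. The AUF1 siRNA library thus held 56.4% of the control level, a log2 ratio of -0.82, which is short of the 2-fold call. Taken from the summed bounds, this ratio would lie between -1.32 and -0.36. HNRNPD ranked 537 from the lowest of 10641 tested genes. The empty vector library held 312.6 FPKM, and every overexpression library was far above it. HNRNPD was 11.8-fold higher with p37 at 3702 FPKM, 10.97-fold with p40 at 3439 FPKM, 15.6-fold with p42 at 4887 FPKM, 11.7-fold with p45 at 3658 FPKM and 9.59-fold with all isoforms at 3007 FPKM. Its processed pseudogene HNRNPDP1 on chromosome X, which shares sequence with it, was listed at 0.75 FPKM with the empty vector and at 5.90 to 14.5 FPKM with overexpression. HNRNPDL, a close relative of HNRNPD, stood at 146.2 FPKM with the empty vector and at 89.4, 116.5, 101.8, 115.3 and 106.5 FPKM with p37, p40, p42, p45 and all isoforms. None of these HNRNPDL ratios, -0.70 to -0.33, passed 2-fold.

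The isoforms differ by exon 2, of 57 nt or 19 codons, and exon 7, of 147 nt or 49 codons, of the 9-exon transcript. Deposited FPKM of single HNRNPD transcripts differed between the overexpression libraries. ENST00000503822 held 2663 FPKM in the p37 library and 2598 FPKM in the p42 library and was listed at 0 in the other libraries. ENST00000509107 held 1518 FPKM in the p40 library, where ENST00000307213 held 1956 FPKM. ENST00000513584 held 1709, 1923 and 1656 FPKM in the p42, p45 and all-isoform libraries and was listed at 0 in the p37 and p40 libraries. ENST00000543098 held 557, 1663 and 711 FPKM in those same 3 libraries. The deposited status of ENST00000509107, ENST00000513584 and ENST00000543098 was LOWDATA in every library, so their levels are uncertain. Transcripts with this status held 74.3% of the deposited HNRNPD FPKM with the control siRNA, 76.3% with the AUF1 siRNA, 73.1% with the empty vector, 0.0% with p37, 43.7% with p40, 46.6% with p42, 100.0% with p45 and 74.2% with all isoforms.

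The AUF1 siRNA library differed from the control siRNA library mainly by genes that were higher. Among the genes highest against both controls were LRFN4, a synaptic adhesion protein (3.44 to 94.1 FPKM, log2 ratio 4.42), HIVEP2, a zinc finger transcription factor (9.01 to 210.4 FPKM, 4.40), and DGKH, a diacylglycerol kinase (11.04 to 150.4 FPKM, 3.65). Also among them were GRIA1, a glutamate receptor subunit (0.17 to 14.3 FPKM, 3.71), RBFOX1, a splicing regulator (1.5 to 30.8 FPKM, 3.67), TENM2, a teneurin adhesion protein (0.43 to 18.98 FPKM, 3.80), and ADGRB2, an adhesion receptor (1.46 to 31.5 FPKM, 3.73). ST18, TDRP and C1RL-AS1 completed this group with ratios of 3.91, 3.91 and 3.87, the last an antisense RNA whose reads cannot be separated from those of its partner. The lowest was DIS3, a catalytic subunit of the RNA exosome (hg19 chromosome 13, 73329540 to 73356234), at 72.3 FPKM with the control and 3.09 FPKM with the AUF1 siRNA, a ratio of -4.16.

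Also among the lowest were IPO9, a nuclear import receptor (180.8 to 12.5 FPKM, -3.75), the snoRNA host gene SNHG7 (35.7 to 3.30 FPKM, -3.09), PHRF1 (-2.88), KDELC1 (-2.80), TBC1D9B (-2.76), DCBLD2 (-2.71), the lipid flippase ATP8A1 (-2.62) and C5orf63 (-2.47). Of 10641 tested genes, 1055 were higher and 339 lower, so that 75.7% of the called genes were higher, and 644 and 118 of them passed against the empty vector as well. A further 87 genes were listed at 0 in the AUF1 siRNA library alone and 100 in the control siRNA library alone. Scaling by the 75th percentile, which moved the median of all genes by -0.13, gave 861 higher and 463 lower, or 65.0% higher. The length-weighted sum gave 734 genes higher and 93 lower, or 88.8% higher. There LRFN4, RBFOX1, GRIA1, TENM2, ADGRB2, ST18, TDRP, C1RL-AS1, DIS3 (-1.99), SNHG7 (-1.48) and KDELC1 (-1.11) stayed past 2-fold, HIVEP2 (0.79, and 0.46 on the summed measure without the length filter), DGKH (0.80), IPO9 (-0.98), PHRF1, DCBLD2 and ATP8A1 did not, and TBC1D9B (0.86) and C5orf63 (0.07) turned in direction.

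Against the control siRNA, 6 gene lists stood apart as lower in the AUF1 siRNA library. They were cytosolic heat shock proteins, mitosis, the DNA damage response, translation factors, ribosomal proteins and the respiratory chain. In this library assembled transcripts of no gene held 18.9% of the length-weighted FPKM of transcripts of 300 nt or more, against 12.9% with the control siRNA, and 86 of 354 olfactory receptor genes were above 0, against 38. The AUF1 siRNA library was deeper than its control, which favours values above 0, and the mean of these olfactory receptor genes was 0.058 against 0.041 FPKM. Antisense and intergenic long noncoding genes had a median of 0.42, against -0.06 for protein-coding genes, and the higher genes spanned 1.86 times the genomic length of other tested genes. Of 15 cytosolic heat shock protein genes 14 had ratios below 0, with a median of -0.50 at percentile 0.09 of matched random lists. HSPH1, a chaperone of the HSP110 family, had 34.5 FPKM with the control and 17.6 with the AUF1 siRNA (-0.93), and DNAJB1 (-0.78), HSPA1B (-0.71, with a near-identical paralog that makes its level uncertain) and the co-chaperone FKBP4 (-0.68) had the next largest ratios. Of 35 mitosis genes 32 were below 0, with a median of -0.35 at percentile 0.12. Among them ANLN, a contractile ring protein, was called lower (106.2 to 34.0 FPKM, -1.62), while the spindle factor TPX2 (-0.87) and the anaphase activator CDC20 (-0.85) were not past 2-fold. Of 31 genes of the DNA damage response 23 were below 0, with a median of -0.25 at percentile 2.11, but of -0.14 at percentile 37.36 among genes with a mean of 20 FPKM or more, where they did not stand apart. The checkpoint kinase ATR was called lower (18.4 to 5.31 FPKM, -1.62) and RAD51D higher (1.52). ATR stood at 5.70 FPKM with the empty vector. Against the empty vector the heat shock and mitosis medians were -0.23 and -0.19, at percentiles 6.88 and 6.41, which no longer stand apart. The DNA damage median was -0.32 at percentile 0.06 there and stayed apart as lower. On the length-weighted sum the heat shock, mitosis and DNA damage medians stayed apart as lower, at percentiles 0.12, 0.0 and 1.4. The length-weighted ratios of ANLN (-0.67), ATR (-0.37) and RAD51D (0.92) were under 2-fold.

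In the same library, of 46 translation factor genes 43 were below 0, with a median of -0.34 at percentile 0.08, and EIF4A2, an RNA helicase of translation initiation, was called lower (203.6 to 91.6 FPKM, -1.14). Against the empty vector the translation factor median was -0.25 at percentile 0.4 and stayed apart as lower. Of 72 ribosomal protein genes 61 were below 0, with a median of -0.32 at percentile 0.33 that lay at 3.78 with a minimum mean of 20 FPKM. Against the empty vector library this median flipped to 0.12 at percentile 99.18, which stood apart as higher. RPS24 was the member called lower (1207 to 572 FPKM, -1.08). Of 38 nuclear-encoded respiratory chain genes 31 were below 0, with a median of -0.30 at percentile 1.24 that flipped to 0.04 against the empty vector. NDUFS1 (30.2 to 7.48 FPKM, -1.88) and UQCRC1 (41.7 to 16.8 FPKM, -1.27), of respiratory complexes I and III, were called lower, as was the ATP synthase subunit ATP5F1A (-1.03). By the length-weighted sum the ribosomal protein, translation factor and respiratory chain medians lay at percentiles 24.7, 8.03 and 2.54 and no longer stood apart, and EIF4A2 (-0.45), RPS24 (-0.77), NDUFS1 (-0.35), UQCRC1 (-0.70) and ATP5F1A (-0.41) were under 2-fold.

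The remaining lists did not stand apart in the knockdown, except under alternatives: histones against the empty vector library, where the median turned to 0.47, the unfolded protein response at percentile 1.93 without a filter on low values, and cervical carcinoma line markers with a lower filter or none. The median was -0.06 over 25 mRNAs known as AUF1 targets and -0.12 over 14 AUF1 relatives and AU-rich-element-binding proteins, where NCL, which encodes nucleolin, was called lower (1014 to 506 FPKM, -1.0). It was -0.18 for base excision, nucleotide excision and mismatch repair, -0.15 for DNA replication, -0.08 for telomere maintenance and -0.08 for p53 targets. Among these, EXO1, a repair exonuclease, was lower (-2.00), and TERT, the telomerase catalytic subunit, was higher (2.25 to 9.30 FPKM, 1.66). RRM2, a ribonucleotide reductase subunit, had 852 FPKM with the control siRNA against 59.9 with the AUF1 siRNA (-3.81), but 83.9 FPKM with the empty vector. Medians were -0.16 for mRNA decay, where the exonuclease XRN1 (33.6 to 6.27 FPKM, -2.25) was lower beside DIS3, and -0.28 for the microRNA machinery, where AGO2 was higher (22.0 to 77.3 FPKM, 1.77). The length-weighted ratios of XRN1 (-0.45), AGO2 (0.15) and EXO1 (-0.68) were not past 2-fold. The other medians were -0.11 for abundant long noncoding RNAs, -0.08 for histones, -0.01 for interferon-stimulated genes, -0.23 for the unfolded protein response, -0.10 for immediate early genes, -0.15 for cholesterol synthesis, -0.05 for glycolysis and hypoxia and -0.21 for splicing. NEAT1, the scaffold RNA of paraspeckles, stood at 12.1 and 18.9 FPKM (0.60), and MALAT1, a nuclear speckle RNA, at 175.2 and 134.0 FPKM (-0.38). Products of RNA polymerase III had 3 tested members with a median of -0.08, and mitochondrially encoded genes were not analysed here.

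The spread between libraries gives a yardstick for these counts. The knockdown pair differed 2-fold in 1394 genes, more than any other of the 28 pairs, and the AUF1 siRNA library took part in the pairs ranked 1 to 5, 7 and 8. The control siRNA and empty vector libraries differed in 771 genes. The overexpression libraries differed from the empty vector in 574 to 832 genes, so that p45 alone exceeded the difference between the controls, and the pairs of single-isoform libraries in 469 to 742 genes.

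**Figure D1:**
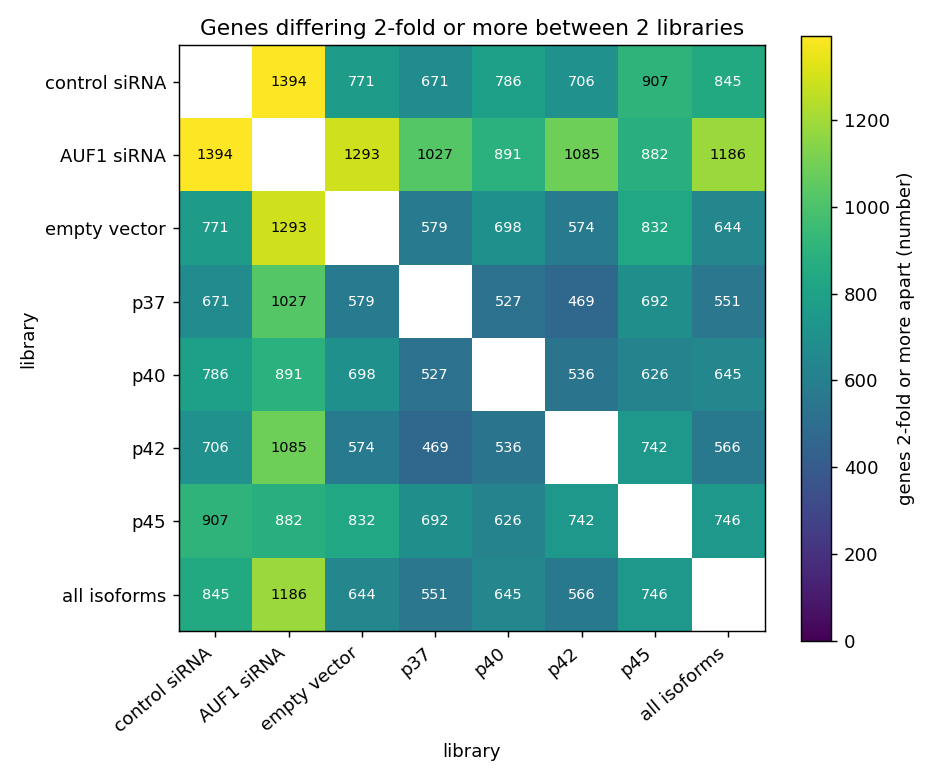
Number of tested genes that differed 2-fold or more between each pair of the 8 libraries, with the colour scale giving the same number. The AUF1 siRNA library differs from the others in 882 to 1394 genes, and the controls differ from each other in 771.

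With p37, HNRNPD and HIVEP2 (9.65 to 214.2 FPKM, log2 ratio 4.34) were highest against the empty vector, followed by PXMP4, a peroxisomal membrane protein (0.91 to 18.3 FPKM, 3.33). TBC1D9B (-3.08) and ATP8A1 (59.1 to 8.05 FPKM, -2.73) were among the lowest. Of 10303 genes, 295 were higher and 284 lower, which turned to 255 and 333 with FPKM as deposited and 288 and 300 with scaling by the 75th percentile. With the length-weighted sum 78 and 48 genes passed, PXMP4 (1.86) stayed past 2-fold, and HIVEP2 (0.57) and ATP8A1 (-0.57) did not. TBC1D9B turned to 0.49 there.

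With p40, the highest genes were MTND1P23 and MTND2P28, nuclear copies of mitochondrial genes on chromosome 1 (1.08 to 1035 FPKM, 8.96, and 1.23 to 458 FPKM, 7.69), and HIST1H1T, a testis linker histone (0.34 to 256.5 FPKM, 7.59). The nuclear copies share sequence with the mitochondrial genome, so their source is uncertain. C1orf21 (102.8 to 5.84 FPKM, -3.92), the deubiquitinase USP34 (136.8 to 16.5 FPKM, -2.98) and LINC02595 (10.2 to 0.56 FPKM, -2.85) were lowest. Of 10370 genes, 410 were higher and 288 lower. The length-weighted sum left 144 and 58 genes, and C1orf21 (-0.80) and USP34 (-0.27) did not.

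With p42, HNRNPD was followed by LSM3P3, a pseudogene that shares sequence with its parent gene and is therefore uncertain (0.11 to 11.1 FPKM, 3.44), and REEP5, a protein of the endoplasmic reticulum (16.5 to 164.2 FPKM, 3.24). HIST1H2BF, 1 of several near-identical H2B histone genes, was lowest (1272 to 9.80 FPKM, -6.88), but the control siRNA library held 62.8 FPKM, which gives -2.56. BOC, a Hedgehog co-receptor (29.5 to 1.64 FPKM, -3.53), and MCF2L2 (-3.14) followed. Of 10298 genes, 303 were higher and 271 lower, which turned to 264 and 334 with FPKM as deposited, against 89 and 42 on the length-weighted sum, where all these named genes stayed past 2-fold.

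With p45, GSTT2B, a glutathione transferase with a near-identical neighbour that makes its level uncertain (8.75 to 342.6 FPKM, 5.14), and WDFY3, an autophagy adaptor (7.63 to 85.3 FPKM, 3.32), were highest with HNRNPD. FRYL (60.5 to 4.30 FPKM, -3.54), BOC (-3.40) and FAM53C (39.9 to 4.18 FPKM, -2.98) were lowest. Of 10463 genes, 522 were higher and 310 lower, or 62.7% higher. FPKM as deposited, which moved the median of all genes by -0.11, gave 430 higher and 397 lower, or 52.0% higher. The length-weighted sum gave 238 and 61 genes, or 79.6% higher, GSTT2B (3.62), BOC (-1.53) and FAM53C (-1.25) among them, while WDFY3 (0.05) and FRYL (-0.62) did not.

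With all isoforms together, DOP1B (2.86 to 37.7 FPKM, 3.33) and SCNN1A, an epithelial sodium channel subunit (0.59 to 13.3 FPKM, 3.17), were highest with HNRNPD. HIST1H2BF (-6.58, or -2.27 against the control siRNA), RBM12B (71.8 to 2.98 FPKM, -4.19) and SLC26A2, a sulfate transporter (41.6 to 2.72 FPKM, -3.52), were lowest. Of 10282 genes, 340 were higher and 304 lower, against 88 and 62 on the length-weighted sum, where DOP1B (0.47) and SLC26A2 (-0.99) did not pass. NEAT1 had ratios of 0.29, 0.29, -0.02, -0.08 and 0.11 in the p37, p40, p42, p45 and all-isoform libraries, and MALAT1 had 0.08, -0.20, -0.23, -0.09 and -0.10.

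Among the lists, histone genes were higher than the empty vector with p37 (0.30), p40 (0.38), p42 (0.50) and p45 (0.22), at percentiles of 99.18 or more, and these medians were -0.16, 0.03, -0.20 and -0.32 against the control siRNA library, so that 3 of them flipped. Ribosomal protein genes were higher with p40 (0.24), p42 (0.10) and p45 (0.29), and flipped to -0.16, -0.25 and -0.12 against the control siRNA library. The p42 median lay at percentile 92.44 with a minimum mean of 20 FPKM and 93.66 without the length filter. The p45 histone median was 0.16 at percentile 97.35, no longer apart, with genes listed at 0 included. RPS28, for example, held 188.8 FPKM with the empty vector, 420.8 with p40, 295.9 with p45 and 442.9 with the control siRNA. Respiratory chain genes were higher with p40 (0.27), which flipped to -0.25 against the control siRNA.

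Cholesterol synthesis genes were lower with p37 (-0.18, percentile 1.61) and p45 (-0.25, percentile 1.98), and against the control siRNA library these medians were -0.13, at percentile 9.96, and -0.34, at percentile 0.12. FDPS, the farnesyl diphosphate synthase, was called lower with p37 (81.4 to 26.8 FPKM, -1.57, or -0.99 on the length-weighted sum), and SQLE, the squalene epoxidase, stood at 36.4 FPKM with the empty vector and 18.4 FPKM with p45 (-0.94). DNA damage response genes were lower with p42 (-0.15, percentile 2.16, but 22.1 against the control siRNA), and splicing factor genes with p45 (-0.16, percentile 2.28, and 1.42 against the control siRNA). Interferon-stimulated genes were lower with all isoforms (-0.29, percentile 2.11), with a median of -0.04 at percentile 39.7 against the control siRNA and of 0.03 against the empty vector when genes with a mean of 1 FPKM were admitted. These calls were also lost under other settings. With a minimum mean of 20 FPKM the p37 and p45 cholesterol medians and the splicing median lay at percentiles 5.16, 9.8 and 3.62, and without a filter on low values the p37 cholesterol, splicing and interferon medians at 13.44, 5.55 and 3.37. The DNA damage median lay at percentile 2.62 with scaling by the 75th percentile, and with a pseudocount of 5 FPKM the splicing and interferon medians lay at 2.94 and 3.68. By length-weighted sum the p37 cholesterol, DNA damage, splicing and interferon medians lay at percentiles 2.97, 5.0, 26.8 and 10.96 and did not stand apart. Further pairs of a list and a comparison stood apart only under an alternative. On the length-weighted sum cholesterol synthesis genes were also lower with p40 (-0.18), p42 (-0.18) and all isoforms (-0.19), and unfolded protein response genes with p37 (-0.14), p40 (-0.19) and all isoforms (-0.18). Against the control siRNA, respiratory chain genes were lower with p37 (-0.36), p42 (-0.29), p45 (-0.32) and all isoforms (-0.49), while their medians against the empty vector were 0.03, 0.07, 0.09 and -0.02. Ribosomal protein genes were lower with p37 (-0.37, or 0.01 against the empty vector) and all isoforms (-0.43, or -0.06), and histones with all isoforms (-0.64, or -0.09), in that comparison. On the length-weighted sum, 2 of these pairs stood apart the other way against the empty vector. Respiratory chain genes were higher with p45 (0.07, percentile 99.7) and ribosomal protein genes with p37 (0.02, percentile 99.89). In all, 19 of 145 tested pairs of a list and a comparison stood apart, where random lists of independent genes would give 7.2. Lists share members and 5 comparisons share the empty vector library, so 7.2 is not the number for unchanged libraries. The control siRNA library itself lay above the empty vector by medians of 0.41 for ribosomal protein genes and 0.64 for histones. The AUF1 target mRNAs had medians of 0.01, -0.03, 0.06, -0.10 and 0.04 in the p37, p40, p42, p45 and all-isoform libraries and did not stand apart. In this list EGR1, an immediate early transcription factor, was higher with p40, p42, p45 and all isoforms (4.56 FPKM with the empty vector to 11.7, 15.4, 10.9 and 10.3 FPKM) and stood at 6.97 FPKM with p37.

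Genes that moved the same way in all 5 overexpression libraries were few. Besides HNRNPD, with a smallest gap of 3.26 on the log2 scale to the higher control, and HNRNPDP1 (1.98), 9 genes were 2-fold or more above both controls in every overexpression library. They were GAPVD1, an endocytic exchange factor (13.5 and 12.7 FPKM in the controls, 55.7 to 116.7 with overexpression), CRY2, a circadian repressor (1.29 and 1.54 FPKM, 6.51 to 12.2), ATP8A2, PACSIN1, CRYBG2, ALG12, ASCC3, TMEM45A (318.2 and 304.0 FPKM, 662 to 956) and SPINK4. By length-weighted sum HNRNPD (3.34) and HNRNPDP1 (1.80) kept the separation and the other 9 did not, with gaps of -0.34 to 0.83. CDON, a Hedgehog co-receptor (25.9 FPKM in both controls, 5.46 to 9.74 with overexpression), FGFR3, a fibroblast growth factor receptor (13.6 and 14.2 FPKM, 1.57 to 3.33), and RNF19A, a ubiquitin ligase (17.2 and 14.5 FPKM, 3.02 to 5.15), were below both controls, and none of the 3 kept this on the length-weighted sum. Against the empty vector alone, 53 genes were higher in all 5 comparisons and 25 lower, where simulated unchanged libraries that share 1 control gave 72.1 and 71.5 on average and independent lists would give 0.00054 and 0.00015. The observed overlap was no larger than in these simulations, and 12 and 2 genes were found on the length-weighted sum. The simulated noise came from the control libraries, whose log2 ratios had a median-based spread of 0.411 on the summed measure. The overexpression libraries differed less from the empty vector, with spreads of 0.302 (p37) to 0.401 (p45). The simulations may thus overstate the overlap of unchanged libraries and cannot decide whether any of it goes beyond the shared control. Without the p45 library, 8 genes were below both controls in the remaining libraries and 40 were lower in all remaining comparisons. Of the 9 genes, GAPVD1 (2.30), CRY2 (1.95), ATP8A2 (1.82), PACSIN1 (2.88), CRYBG2 (2.57), ALG12 (1.74), ASCC3 (1.08) and TMEM45A (1.98) were also higher in the AUF1 siRNA library than with the control siRNA, and FGFR3 (-1.55) and RNF19A (-1.76) were also lower there. All these genes were chosen by their separation from that same control siRNA library, which favours such a shared direction.

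The isoforms differed from one another in a median of 581 genes per pair. The libraries with exon 2 (p40 and p45) were separated 2-fold from those without it (p37 and p42) in 68 genes, those with exon 7 (p42 and p45) from those without it in 37 genes, and the remaining split, which follows neither exon, in 42 genes. The p37 and p42 libraries were also deeper, at 0.319 and 0.345 coverage per 1 FPKM, against 0.262 with p40 and 0.215 with p45. In the exon 2 split, exon 2 and depth thus cannot be told apart. The translation initiation factor subunit EIF3B and C17orf49 were among the genes higher with exon 2, and GLI1, the Hedgehog transcription factor, and HIST1H2BD were among those lower. TMEM50B, PIP5K1B and DICER1 were higher with exon 7, and BOC, ONECUT2 and HIST2H2BF lower. These genes are among those with the largest gaps and were chosen after their values were seen. These splits held 24, 6 and 5 genes by length-weighted sum. DICER1, BOC, ONECUT2 and GLI1 did not keep their separation there, while C17orf49, HIST1H2BD, TMEM50B, PIP5K1B and HIST2H2BF did. EIF3B was not among the genes with the largest gaps on that measure. The all-isoform library lay 2-fold outside the range of the single isoforms in 96 genes, and each single-isoform library outside the range of the others in 67 (p37), 74 (p40), 72 (p42) and 121 (p45).

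Genes called in the knockdown and in overexpression moved more often in the same direction than in opposite directions. Both directions combined, 120 genes moved the same way and 78 oppositely with p37, 182 and 75 with p40, 123 and 84 with p42, 263 and 81 with p45 and 141 and 92 with all isoforms. With p45, 222 genes were higher in both, where independent lists would share 50.1, and 140 on the length-weighted sum, where 15.5 would be shared. Opposite movement exceeded independent lists as well. On the summed measure 56 genes were higher in the knockdown and lower with p42, against 24.7, and 38 were lower in the knockdown and higher with p45, against 16.9. No library is shared between these comparisons. Independent lists, however, treat every gene as equally likely to be called. In the knockdown 12.6% of genes at 5 to 20 FPKM were higher, against 6.2% at 20 FPKM or more, and with p45 6.0% against 3.6%. An excess over independent lists thus cannot show a shared response by itself. Across genes, which are not independent replicates, the ratios correlated with r of 0.06 to 0.19, and with the controls exchanged with r of 0.05 to 0.24. On the length-weighted sum r was 0.10 to 0.33, and 0.09 to 0.36 with the controls exchanged. Opposite movement in the direction of higher in the knockdown and lower in overexpression was largest for DZANK1, FNIP2, CLOCK (7.0 to 23.1 FPKM in the knockdown, 53.9 with the empty vector and 7.10 to 27.0 with overexpression), THADA and GLI1. DNAH7, USP37, NCDN, MARC1 and the ribosome biogenesis factor NSA2 moved the other way. For all of them but NSA2 and GLI1, the knockdown ratio on the length-weighted sum was under 1 in size.

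Markers of other cell lines were examined in every library. Fibroblast markers had 5 tested members in the knockdown with a median of 0.37 at percentile 87.1, and COL5A1, a collagen chain, was called higher (6.97 to 15.6 FPKM, 1.06). In the overexpression comparisons they had 4 tested members and medians of -0.12 to 0.17. Cervical carcinoma line markers had a knockdown median of 0.01 at percentile 64.0, with ANXA3 (9.77 to 27.4 FPKM) and CD44 (3.32 to 9.17 FPKM) higher, and medians of -0.08 to 0.22 with overexpression. HEK293 line genes had a knockdown median of 0.09 at percentile 83.2, with the kidney transcription factor PAX2 (3.91 to 17.2 FPKM, 1.89) and ZIC2 (9.17 to 20.7 FPKM, 1.09) higher, and medians of -0.13 to 0.18 with overexpression. None of these lists stood apart on the summed measure with the fixed filter. Under alternatives, the cervical carcinoma line markers stood apart in the knockdown with a minimum mean of 1 FPKM (median 0.63, percentile 99.33) or no filter on low values (0.53, 98.78), and with p37 on the length-weighted sum (-0.22, 1.64) or without that filter (-0.22, 1.81). The HEK293 line genes stood apart with p40 against the control siRNA (0.42, 99.5).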

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

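The tests of depth, of the other splits of the libraries, of reads moved between transcripts and of the empty vector library, and those on the length-weighted sum, were chosen only after the results they bear on had been seen, and the tests of GC content and unspliced RNA before.

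Signal outside the genes compared was above both controls in 3 values. Assembled transcripts that belong to no gene held 18.9% of the length-weighted FPKM of transcripts of 300 nt or more in the AUF1 siRNA library and 19.5% in the p42 library, against 12.9% with the control siRNA and 8.9% with the empty vector. Transcripts under 300 nt held 82.0% of all length-weighted FPKM in the all-isoform library, against 81.3% and 69.9% in these controls.

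In the AUF1 siRNA library 75.7% of the 2-fold genes were higher than with the control siRNA. GC content as the whole cause is argued against, because 77.6% were higher after the median of each of 20 GC bins was taken off, and 91.8% on the length-weighted sum. Depth as the whole cause is argued against by direct comparison with the p37 library, about as deep, and the deeper p42 library, where at least 72.4% were higher with the AUF1 siRNA, 90.3% on the length-weighted sum and at the lowest 62.0%, with a minimum mean of 20 FPKM. Depth as a part of it stays open, but the share of higher genes did not follow depth. On the length-weighted sum 67.9% of the 2-fold genes of the p42 library and 61.9% of the p37 library were higher than in the shallower empty vector library. In the p45 library, about as shallow as the empty vector, 79.6% were higher. Unspliced RNA may contribute: the higher genes spanned 1.86 times the genomic length of other tested genes at the same expression, a value between the bounds set for and against, and with 1 library for the AUF1 siRNA, unspliced RNA and an effect of the siRNA itself cannot be told apart.

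For the genes higher in all 5 overexpression libraries, HNRNPD and HNRNPDP1 separate by design, and without them the real split gave 9 genes and the highest of the other splits 8. That is 1 of 21 splits, the smallest share that they allow. On the length-weighted sum the real split gave 0 genes and the highest other 1, and a count of 0 cannot set the real split apart. Chance is therefore not excluded for the 9 genes. Nor is it for the 3 lower genes, since 12 of 21 splits gave as many and the highest other gave 5. A candidate explanation is that reads moved between transcripts of different length, because 2 of the 11 genes, HNRNPD and its pseudogene HNRNPDP1, kept the separation on the length-weighted sum. An effect of AUF1 overexpression on the other genes stays open. Of them, 8 were also higher in the AUF1 siRNA library than with the control siRNA. This cannot weigh against such an effect, because the genes were chosen for low values in that same control library.

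Ribosomal protein and histone genes were higher in the p40 and p45 libraries than with the empty vector. The control siRNA library also lay above the empty vector, by a median of 0.41 for ribosomal protein genes and 0.64 for histone genes. These exceed the shifts with p40 (0.24 and 0.36) and p45 (0.29 and 0.25) over the same members. A candidate explanation is that a control library stands apart, but which one cannot be told. The control siRNA library was the highest for both lists. For ribosomal protein genes p37 (0.01), p42 (0.10), all isoforms (-0.06) and AUF1 siRNA (0.12) lay nearer the empty vector. For histone genes all isoforms lay at -0.09, while p37 (0.30), p42 (0.50) and AUF1 siRNA (0.42) lay above the empty vector. An effect of the isoforms stays open and was not tested apart from the control.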

How the results depend on the processing

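The length-weighted sum, the inclusion of genes listed at 0 and the omission of the p45 or p40 library were chosen only after the data had been seen. No paired analysis was possible because each group held 1 library and the labels give no pairing. Of the values that answer a comparison, 206 stayed within 1.5 times of the reported count, or within the range from the summed transcript bounds for HNRNPD, under an alternative and 170 did not. No such value left this range with scaling by the 75th percentile, FPKM as deposited or the other control library. Of the list results, 1489 stayed apart or not apart as reported, 31 lost the call, 49 gained it and 10 that stood apart turned in direction. Medians of lists that did not stand apart had another sign in 106 of the first and 5 of those that gained the call. Of the named-gene results, 541 kept direction and call, 17 lost the call and 3 turned. The number of reads behind each value is unknown, so depth limits low genes most, and a gene listed at 0 may be below detection at this depth or a failed estimate, as 17 genes in all overexpression libraries were higher when zeros were included, against 11.

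A pseudocount of 5 FPKM shrinks the ratios of low genes and lowered the counts. Higher genes numbered 653 in the knockdown, 151 with p37, 212 with p40, 166 with p42, 267 with p45 and 168 with all isoforms. Lower genes numbered 186 in the knockdown, 156 with p37, 174 with p40, 150 with p42, 169 with p45 and 158 with all isoforms. All overexpression libraries differed from both controls in 3 higher. The overexpression comparisons shared 18 higher and 15 lower. Isoform differences gave a median of 316 per isoform pair, 24 for the exon 7 split, 34 for the exon 2 split, 23 for the remaining split and 42 outside the single-isoform range. Genes that moved the same way in knockdown and overexpression numbered 49 with p37, 77 with p40, 44 with p42, 91 with p45 and 41 with all isoforms. Opposite movement was found for 28 with p37, 33 with p40, 26 with p42, 37 with p45 and 35 with all isoforms.

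With a minimum mean of 1 FPKM more genes were tested. Higher genes numbered 2454 in the knockdown, 602 with p37, 904 with p40, 610 with p42, 1161 with p45 and 714 with all isoforms. Lower genes numbered 549 in the knockdown, 556 with p37, 515 with p40, 544 with p42, 538 with p45 and 551 with all isoforms. Against both controls, genes in all overexpression libraries numbered 17 higher. The overexpression comparisons shared 85 higher and 42 lower. Isoform differences gave a median of 1230 per isoform pair, 66 for the exon 7 split, 123 for the exon 2 split, 64 for the remaining split and 148 outside the single-isoform range. Genes that moved the same way in knockdown and overexpression numbered 222 with p37, 381 with p40, 215 with p42, 513 with p45 and 285 with all isoforms. Those that moved oppositely numbered 157 with p37, 140 with p40, 154 with p42, 137 with p45 and 179 with all isoforms.

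With no filter on low values still more genes were tested. Higher genes numbered 2665 in the knockdown, 669 with p37, 997 with p40, 671 with p42, 1247 with p45 and 794 with all isoforms. Lower genes numbered 584 in the knockdown, 612 with p37, 554 with p40, 606 with p42, 587 with p45 and 604 with all isoforms. Against both controls, genes in all overexpression libraries numbered 17 higher and 5 lower. The overexpression comparisons shared 85 higher and 49 lower. Isoform differences gave a median of 1347.5 per isoform pair, 68 for the exon 7 split, 129 for the exon 2 split, 65 for the remaining split and 166 outside the single-isoform range. Genes that moved the same way in knockdown and overexpression numbered 228 with p37, 391 with p40, 220 with p42, 527 with p45 and 289 with all isoforms. Those that moved oppositely numbered 164 with p37, 143 with p40, 158 with p42, 141 with p45 and 183 with all isoforms.

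With a minimum mean of 20 FPKM fewer genes were tested, and interferon-stimulated genes gave no value for all isoforms. Higher genes numbered 276 in the knockdown, 105 with p37, 147 with p40, 113 with p42, 161 with p45 and 118 with all isoforms. Lower genes numbered 137 in the knockdown, 101 with p37, 108 with p40, 92 with p42, 109 with p45 and 104 with all isoforms. All overexpression libraries differed from both controls in 4 higher and 0 lower. The overexpression comparisons shared 21 higher and 4 lower. Isoform differences gave a median of 201 per isoform pair, 18 for the exon 7 split, 19 for the exon 2 split, 15 for the remaining split and 36 outside the single-isoform range. Genes that moved the same way in knockdown and overexpression numbered 31 with p37, 43 with p40, 32 with p42, 57 with p45 and 33 with all isoforms. Opposite movement was found for 21 with p37, 23 with p40, 27 with p42, 28 with p45 and 33 with all isoforms.

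Under the length-weighted sum counts were lower, and the cause was not tested. Higher genes numbered 78 with p37, 144 with p40, 89 with p42, 238 with p45 and 88 with all isoforms. Lower genes numbered 93 in the knockdown, 48 with p37, 58 with p40, 42 with p42, 61 with p45 and 62 with all isoforms. The log2 ratio of HNRNPD was 4.01 with p45 and 3.71 with all isoforms. All overexpression libraries differed from both controls in 2 higher and 0 lower. The overexpression comparisons shared 12 higher and 2 lower. Isoform differences gave a median of 142 per isoform pair, 6 for the exon 7 split, 24 for the exon 2 split, 5 for the remaining split and 17 outside the single-isoform range. Genes that moved the same way in knockdown and overexpression numbered 22 with p37, 70 with p40, 22 with p42, 145 with p45 and 35 with all isoforms. Opposite movement was found for 17 with p37, 17 with p40, 16 with p42, 11 with p45 and 13 with all isoforms.

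Inclusion of genes listed at 0 adds genes. All overexpression libraries differed from both controls in 17 higher. The overexpression comparisons shared 81 higher. Isoform differences gave 68 for the exon 7 split and 78 for the remaining split. In knockdown and overexpression, opposite movement was found for 119 with p37, 114 with p40, 130 with p42 and 127 with p45.

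Omission of the length filter also moved values, and the cause was not tested. Against both controls, genes in all overexpression libraries numbered 5 lower. Isoform differences gave 146 outside the single-isoform range. In knockdown and overexpression, opposite movement was found for 122 with p37, 128 with p42 and 128 with p45. With a pseudocount of 0.1 FPKM 6 genes were lower in all overexpression libraries. Without the p45 library 8 genes were lower in the remaining overexpression libraries and these shared 40 lower genes. Fewer libraries then had to meet the threshold, but the same holds without the p40 library, where these counts were 4 and 36. The number of libraries alone thus does not account for the difference between these omissions, and its cause was not tested.

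Direction turned in 10 list results that stood apart and 3 named-gene results. The control siRNA library lay above the empty vector by medians of 0.41 for ribosomal protein genes and 0.64 for histones. These exceed in size the ribosomal protein and histone medians that turned, so those turns follow the difference between the controls. Which control stands apart cannot be told, and the cause of the other turns was not tested. With the other control library the ribosomal protein medians became 0.12 in the knockdown, -0.16 with p40, -0.25 with p42 and -0.12 with p45, the respiratory chain medians 0.04 in the knockdown and -0.25 with p40, and the histone medians -0.16 with p37, -0.20 with p42 and -0.32 with p45. The 5 medians that gained the call with another sign did so there: ribosomal proteins with p37 (0.01 to -0.37), the respiratory chain with p37 (0.03 to -0.36), p42 (0.07 to -0.29) and p45 (0.09 to -0.32), and histones in the knockdown (-0.08 to 0.47). With a minimum mean of 1 FPKM the interferon median for all isoforms was 0.03. The length-weighted ratio of TBC1D9B was 0.86 in the knockdown and 0.49 with p37, and that of C5orf63 was 0.07 in the knockdown.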

Other observations

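The genes and groups in this part were chosen after their values were seen, and no test was run on them. Further genes were higher with the AUF1 siRNA on both the summed and the length-weighted measure. CACNA1E, a voltage-gated calcium channel subunit, rose from 0.97 to 14.2 FPKM (log2 ratio 2.95) and KCNIP1, a potassium channel partner, from 5.85 to 46.8 FPKM (2.80). PCSK5, a proprotein convertase, rose from 14.0 to 115.8 FPKM (2.96), LSP1 from 3.91 to 40.6 FPKM (3.09), NINJ2 from 6.63 to 82.3 FPKM (3.45) and GALNT9, a glycosyltransferase, from 2.41 to 38.1 FPKM (3.52). Each of them was 2-fold or more above the empty vector library as well, and their length-weighted ratios to the control siRNA were 2.86 to 3.28. ZBTB20, a zinc finger repressor, fell from 105.3 to 19.97 FPKM (-2.34, and -2.09 length-weighted).

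A larger share of long noncoding genes than of protein-coding genes was higher in this library, and a smaller share was lower. The groups were not matched on expression, and 12.6% of genes at 5 to 20 FPKM were higher, against 6.2% at 20 FPKM or more. Of 728 antisense and intergenic long noncoding genes 207 were higher and 14 lower, with a median of 0.42, against 780 and 296 of 9190 protein-coding genes, with a median of -0.06. Antisense genes are uncertain here, because strand was not used. With p45, 72 of 691 such noncoding genes were higher and 19 lower. Of 354 olfactory receptor genes, which are silent in most tissues, 86 were above 0 in the AUF1 siRNA library, 38 with the control siRNA, 43 with the empty vector and 46 to 63 with overexpression. Such counts depend on depth, and the AUF1 siRNA library was deeper than both controls. The mean of these genes was 0.058 FPKM there, 0.041 with the control siRNA, 0.034 with the empty vector, 0.054 with p40, 0.056 with p45 and 0.033 to 0.042 in the other overexpression libraries. The 1055 genes higher in the knockdown had a median of 17.8 FPKM in the AUF1 siRNA library, 5.0 with the control siRNA and 7.1 with the empty vector. It was 8.2 with p37, 9.4 with p40, 8.1 with p42, 10.7 with p45 and 8.6 with all isoforms. These genes were chosen for low values with the control siRNA, which favours higher values in every other library.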
